A study of Mus musculus with 12 samples.

How the data were processed

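Messenger RNA was measured in 12 libraries of mouse 4T1 cells: control and PBRM1 KO cells, untreated or after 4 days with 5 ng/ml TGFβ1, in 3 biological replicates per group, per the labels' protocols. Libraries were primed on the poly(A) tail, tagmented, read single-end and stranded at the 3′ end and deduplicated by molecular identifier, per the labels' protocols. Fastp 0.24.0, STAR 2.7.11, SAMtools 1.22.1, featureCounts, Subread 2.1.1, edgeR 3.38.4 and genome build mm39 were used, per the submitters' processing notes. The version of featureCounts, its settings, the annotation release and the order of steps were not given in the sources used here. The deposited counts were of the expected count kind, per the file headers and values: 91.8% of cells were whole with a tolerance of 0 and the others, with any decimal part, fractional, so reads that fit several genes appear to have been shared out. The deposited CPM values were, per the file headers, CPM by name, and equalled count over library total with a largest difference of 4.85e-06. The 92 ERCC spike-in entries held 0 counts.

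The table held 78317 genes, 21909 of them without a symbol. Library totals ran from 9265690 to 11250800 counts, and 22908 to 24402 genes were detected per library. Counts were rounded to whole numbers, genes were filtered with filterByExpr, which left 14012, and libraries were scaled by TMM. The common biological coefficient of variation was 12.5%. Log CPM of replicates correlated at 0.978 to 0.992, and the chi-square per gene between replicates was 3.76 to 23.0, so no pair was a copy. The share of mitochondrial transcripts, share of the top 20 genes, genes detected and totals were compared between groups with 16 exact permutation tests, whose adjusted p was 0.96 or more; groups of 3 can reach no less than 0.1 before adjustment.

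The comparisons, tests, lists and alternatives were chosen before the data were examined, apart from those named below as chosen afterwards. Differential expression used edgeR 4.0.16 in R 4.3.3 with 1 mean per group on all 12 libraries, the quasi-likelihood F test (not robust) and Benjamini-Hochberg adjusted p below 0.05. The 5 contrasts were TGFβ1 in control cells, TGFβ1 in PBRM1 KO cells, genotype without TGFβ1, genotype with TGFβ1 and their interaction. The error beside a log2 fold change is the fold change over the square root of F. The 25 lists held 653 genes, and 23 lists with at least 5 tested genes were tested with camera in limma 3.58.1 at the preset correlation of 0.01. Fry, which asks whether the genes of a list move 1 way on balance without comparing them with other genes, is summed up in the closing section and given for 2 lists in the report. Camera with a correlation estimated per list stood beside the main test, and p was adjusted over the 23 lists of a contrast. Adjustment over the list alone means Benjamini-Hochberg over its tested members. Leukocyte and endothelial markers had 2 tested genes each and were not tested as lists; the leukocyte sum is given in the closing section.

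Genes were named by a rule: in each contrast the 10 largest rises and falls that passed, had at least 10 CPM, separated all libraries of both groups and carried a plain symbol; up to 4 members per direction of each list by p, or 2 where none passed; and a panel of 11 genes, of which 10 are reported here (Pbrm1, Cdh1, Epcam, Vim, Fn1, Snai1, Snai2, Zeb1, Zeb2, Smad7). Acod1 and Nos2 were named after their values were seen. For genes with 3 counts or fewer in a group, folds are ratios of summed counts with exact binomial 95% intervals, or a bound with a floor of 3 counts. Of the genes in the text, Fn1, Cldn4, Ldha, Eno1, Pgk1, Idi1, Sc5d, Phgdh, Psat1, Ftl1, H2-D1 and Tubb2b had fractional counts in 10 or more libraries, so reads shared with other genes entered their values. Overlaps were compared with the product of the margins, correlations carry a jackknife SE over 12 libraries, and the contrasts that share untreated control libraries were set against 20 simulations. The untreated control group of 3 was too small to split.

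The labels number biological replicates without saying that a number marks a shared day. Deviations from the group means of same-numbered libraries correlated at 0.201, 0.139 and 0.202 for TGFβ1 in PBRM1 KO cells and at 0.396, 0.416 and 0.726 for genotype with TGFβ1. All lay over 0.1, so these 2 contrasts were taken as paired from the data and their blocked values stand beside them where they change a call or move a count by over 1.5 times. The counts of calls of the blocked fit had been seen before this check was settled.

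Alternatives were RLE and library-size scaling, no filter on low counts, at least 10 CPM, DESeq2 1.42.0, limma-voom, only the 6 libraries of a contrast, the replicate number as a block, adjusted p below 0.01 for overlaps and each library left out in turn. Those without both TGFβ1 replicate 3 libraries and with unrounded counts were added after the data were seen. Each contrast was tested on simulated data with 200 changed genes. For TGFβ1 in control and PBRM1 KO cells 34.3% and 38.8% of 1.5-fold changes, 68.7% and 64.2% of 2-fold changes and 87.9% and 90.9% of 4-fold changes were recovered. For genotype without and with TGFβ1 the shares were 37.3% and 23.9%, 77.6% and 73.1%, and 89.4% and 95.5%. The interaction recovered 11.9%, 53.7% and 84.8%, and each contrast made 4 to 8 false calls. A mitosis list moved by log2 0.4 was called (camera adjusted p = 1.32e-43, adjusted p = 5.28e-06 with an estimated correlation) with 0 of 22 other lists. In all these simulations genes and libraries were drawn independently around the group means. The 0 of 22 therefore says nothing about false calls of lists whose members vary together. Genome coordinates were not used here, since the reference at hand was another build than mm39.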

Results

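The series measured messenger RNA in 4T1, a mouse line of triple-negative mammary carcinoma. PBRM1, encoded by Pbrm1, is the bromodomain-rich subunit of the PBAF form of the SWI/SNF chromatin remodelling complex. TGFβ1 is a secreted cytokine that signals through SMAD2 and SMAD3 and moves many epithelial cells towards a mesenchymal state. Control and PBRM1 knockout (KO) cells were sampled untreated and after 4 days with 5 ng/ml TGFβ1, with n = 3 biological replicates in each of the 4 groups. Each library was a set of deduplicated 3′ end counts per gene, and library totals ran from 9265690 to 11250800 counts. Of 78317 genes in the table, 35661 had any count and 14012 were tested. The untreated samples were named as 0 h, so TGFβ1 and the 4 days were not separated.

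Pbrm1 was counted at 328, 261 and 258 CPM in the untreated control libraries and at 290, 292 and 276 CPM in the control libraries with TGFβ1. The PBRM1 KO libraries held 245, 207 and 222 CPM untreated and 274, 233 and 222 CPM with TGFβ1. The genotype difference was log2 −0.33 ± 0.10 without TGFβ1 (edgeR adjusted p = 0.349) and −0.25 ± 0.10 with it (adjusted p = 0.513). Where the gene was edited was not given in the sources used here, and a 3′ end count need not read that part, so these values check neither the edit nor the loss of protein. TGFβ1 left Pbrm1 at log2 0.02 ± 0.10 in control cells (adjusted p = 0.941) and 0.10 ± 0.10 in PBRM1 KO cells (adjusted p = 0.582).

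Mitochondrially encoded transcripts took 6.14 ± 0.188% of counts in untreated control libraries and 6.09 ± 0.412% with TGFβ1, and 6.17 ± 0.609% and 5.93 ± 0.441% in the PBRM1 KO groups (mean ± SD, n = 3). The first principal component held 53.2% of the variance and separated the libraries by TGFβ1. The second held 11.3% and separated control libraries (3.54 to 22.4) from PBRM1 KO libraries (−19.3 to −5.54). On an axis with untreated cells at 0 and TGFβ1 replicates 1 and 2 of the other genotype at 1, TGFβ1 replicates 1 and 2 lay between 0.843 and 1.07. Replicate 3 lay at 0.328 in control and 0.463 in PBRM1 KO cells, and untreated libraries lay between −0.0637 and 0.125. The SMAD target list had the same order: its median was log2 0.32 above untreated control cells in control TGFβ1 replicate 3, against 1.07 and 1.10 in replicates 1 and 2. In PBRM1 KO cells the same medians were 0.40 in replicate 3 and 1.11 and 0.94 in replicates 1 and 2.

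In control cells TGFβ1 raised its own feedback and target genes. Ccn2, a matricellular growth factor, rose by log2 2.49 ± 0.27 (adjusted p = 0.000226), and Smad7, the inhibitory SMAD, by 1.02 ± 0.22 (adjusted p = 0.0143). Of 18 tested TGFβ-SMAD targets 11 rose and 0 fell, and 16 rose when adjusted over the list alone. The list was higher with camera adjusted p = 5.15e-12 at the preset correlation and adjusted p = 0.158 with an estimated correlation. That last value was adjusted p = 0.0061 without both TGFβ1 replicate 3 libraries. Of 6 BMP-SMAD and Id genes, 0 rose and 1 fell: Id2, a repressor of helix-loop-helix factors, by log2 −0.77 ± 0.19. Adjusted over the list alone 1 rose and 1 fell, and the list did not pass (camera adjusted p = 0.354). Among 20 YAP-TEAD targets 4 rose, with Amotl2 at 1.16 ± 0.17, Ankrd1 at 0.72 ± 0.12 and Lats2 at 0.58 ± 0.09, and 5 rose and 1 fell adjusted over the list alone. This list was higher with camera adjusted p = 0.000224 and adjusted p = 0.0968 with an estimated correlation.

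**Figure D1:**
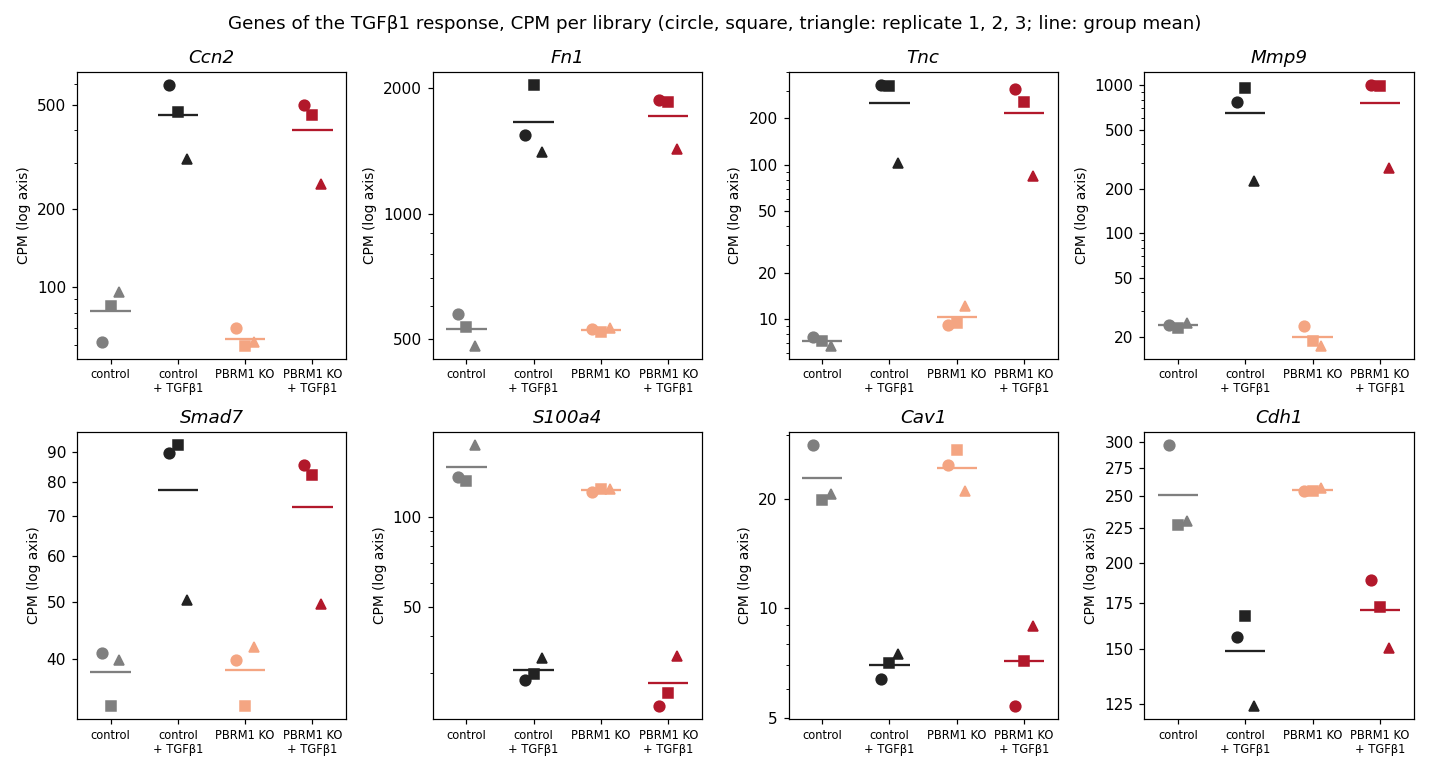
CPM of 8 genes in the 4 groups on log axes, 1 point per library and n = 3 per group. The group means of Ccn2 were 81.0 and 457 CPM in control cells and 63.8 and 401 CPM in PBRM1 KO cells, untreated and with TGFβ1.

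Of 22 mesenchymal identity genes 8 rose and 1 fell in control cells, or 10 and 2 adjusted over the list alone. Fn1, fibronectin, went from 530 ± 46.3 to 1663 ± 332 CPM (log2 1.65 ± 0.13, adjusted p = 2.49e-05), and Itgb3, integrin β3, rose by 4.02 ± 0.62. Snai1 and Zeb2, repressors of Cdh1, rose by 0.86 ± 0.23 and 0.83 ± 0.09. S100a4, a calcium-binding protein of motile cells, fell by 2.27 ± 0.15. Vim was at log2 0.06 ± 0.14 (adjusted p = 0.825), Zeb1 at 0.85 ± 0.39 (adjusted p = 0.201) and Snai2 at −0.64 ± 0.69 (adjusted p = 0.614). The list was higher (camera adjusted p = 0.000121, adjusted p = 0.113 with an estimated correlation). Of 36 epithelial genes 13 fell and 1 rose, or 14 and 1 adjusted over the list alone. Cdh1, E-cadherin, went from 251 to 149 CPM (log2 −0.75 ± 0.12), Krt19 fell by 1.05 ± 0.15 and Perp by 0.95 ± 0.09, while Lsr rose by 0.29 ± 0.08 and Epcam was at 0.02 ± 0.15 (adjusted p = 0.944). The epithelial list was lower with camera adjusted p = 1.03e-07 and adjusted p = 0.142 with an estimated correlation.

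Both matrix lists were higher with TGFβ1 in control cells at the preset correlation. Of 37 collagen and matrix assembly genes 13 rose and 1 fell, or 18 and 2 adjusted over the list alone. Tnc, tenascin C, went from 7.16 to 252 CPM (log2 5.13 ± 0.52), Postn rose by 2.40 ± 0.46 and Lamb1 by 0.68 ± 0.09, and Lama5 fell by 0.38 ± 0.10. The list was higher with camera adjusted p = 4.63e-08 and adjusted p = 0.291 with an estimated correlation. Of 25 matrix proteases and inhibitors 8 rose and 3 fell, or 11 and 4 adjusted over the list alone. Mmp9, a gelatinase, went from 23.9 to 652 CPM (log2 4.76 ± 0.54), and Mmp13 and Mmp10 rose by 4.67 ± 0.32 and 3.60 ± 0.32, while Adam8 fell by 1.84 ± 0.18. Camera gave adjusted p = 6.52e-05 for the protease list and adjusted p = 0.0968 with an estimated correlation. Of 22 actin and contractility genes 5 rose and 0 fell, with Tln1 at 0.67 ± 0.17 and Vasp at 0.38 ± 0.08, and 9 rose adjusted over the list alone (camera adjusted p = 0.000413, adjusted p = 0.49 with an estimated correlation).

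Cell division and metabolic lists were lower with TGFβ1 in control cells at the preset correlation, and none passed with an estimated one. Of 30 mitosis genes 5 fell and 0 rose, among them Nusap1, a spindle protein, by log2 −0.60 ± 0.11 and Cdc20 by −0.40 ± 0.11, and 18 fell adjusted over the list alone (camera adjusted p = 1.29e-08, adjusted p = 0.158 with an estimated correlation). Of 32 S phase genes 3 fell, with Mcm5 at −0.42 ± 0.11, and 6 fell adjusted over the list alone (camera adjusted p = 4.85e-06, adjusted p = 0.482 with an estimated correlation). The S phase median lay at −0.03 in control TGFβ1 replicate 3 and at −0.35 and −0.41 in replicates 1 and 2. Of 32 hypoxia and glycolysis genes 13 fell and 1 rose, or 15 and 3 adjusted over the list alone. Ldha fell by 0.50 ± 0.11, Eno1 by 0.34 ± 0.06 and Car9 by 1.14 ± 0.19, while Vegfa rose by 2.03 ± 0.45 (camera adjusted p = 2.23e-05, adjusted p = 0.158 with an estimated correlation). Ldha, Eno1 and Pgk1 had fractional counts in all 12 libraries, so reads shared with other genes entered their values. Cholesterol synthesis was lower with 2 of 24 genes falling and 5 adjusted over the list alone, among them Sqle by −0.52 ± 0.12 (camera adjusted p = 0.000137, adjusted p = 0.481 with an estimated correlation). In oxidative phosphorylation 1 of 34 genes fell, Atp5f1a by −0.27 ± 0.07, and 0 fell adjusted over the list alone (camera adjusted p = 0.00075, adjusted p = 0.516 with an estimated correlation).

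Of 25 chemokine, cytokine and NF-κB genes 9 rose and 1 fell in control cells, or 11 and 1 adjusted over the list alone. Il1a, which encodes interleukin 1α, went from 107 to 493 CPM (log2 2.20 ± 0.24), Lcn2, lipocalin 2, rose by 1.39 ± 0.26 and Ptgs2 by 0.90 ± 0.18, and Cxcl5, a neutrophil chemokine, fell by 2.28 ± 0.62. The list was higher with camera adjusted p = 0.000413 and adjusted p = 0.134 with an estimated correlation, and without both TGFβ1 replicate 3 libraries it did not pass (adjusted p = 0.0707). In MHC class I presentation 1 of 21 genes rose, Pdia3 by 0.32 ± 0.09, and 0 rose adjusted over the list alone (camera adjusted p = 0.00159, adjusted p = 0.516 with an estimated correlation). Of 34 interferon-stimulated genes 0 rose and 3 fell (Oas3, Oasl1 and Ifit2; Oasl1 by −0.86 ± 0.25), also 0 and 3 adjusted over the list alone, although the list median was log2 0.41 and the camera direction was up (adjusted p = 0.118). The interferon median was −0.45 in control TGFβ1 replicate 3 and 0.51 and 0.91 in replicates 1 and 2; without both replicate 3 libraries 21 of the 34 rose, 3 fell and camera gave adjusted p = 1.53e-05.

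The other lists did not pass in control cells. Of 26 unfolded protein response and ATF4 targets 9 rose and 3 fell, with Xbp1 at log2 0.67 ± 0.15, Pdia6 at 0.49 ± 0.07 and the serine synthesis gene Phgdh at −0.58 ± 0.13; adjusted over the list alone 9 rose and 5 fell (adjusted p = 0.493). Its median (−0.00) and mean (−0.04) were below 0 while the camera direction was up. Of 14 tumour-initiating and mammary stem markers 3 rose and 2 fell, or 4 and 3 adjusted over the list alone (adjusted p = 0.354): Jag1, a Notch ligand, rose by 2.56 ± 0.37, and Itga6 and Notch1 fell by 0.98 ± 0.19 and 0.77 ± 0.15. Of 17 cell cycle inhibitors and p53 targets Cdkn1a, the inhibitor p21, rose by 0.85 ± 0.25 and Perp fell (adjusted p = 0.931, direction down with a median of 0.03). The NRF2 targets had 1 rise and 1 fall among 22 (Osgin1 0.44 ± 0.12, G6pdx −0.45 ± 0.10; adjusted p = 0.26), and the SWI/SNF subunits 1 rise among 27 (Bcl11a 0.64 ± 0.18, adjusted p = 0.316). Fibroblast markers had 1 fall among 9 (Gsn −0.43 ± 0.09, adjusted p = 0.366) and the mitochondrially encoded transcripts 0 of 15 (adjusted p = 0.366). Adjusted over the list alone, rises and falls were 2 and 1 for p53 targets, 1 and 1 for NRF2 targets and for fibroblast markers, and 0 and 0 for SWI/SNF subunits and mitochondrial transcripts.

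Outside these groups the largest rises in control cells with at least 10 CPM were Prdm1, the repressor BLIMP1, at log2 5.78 (adjusted p = 0.0111), Hsd11b2 at 4.62 ± 0.57, Cd40 at 3.99 ± 0.63, Smoc1 at 3.92 ± 0.68 and Mab21l4 at 3.74 ± 0.89. The largest falls were Fgfbp1 at −2.53 ± 0.43, Dlk2 at −2.52 ± 0.45, Padi1 at −2.26 ± 0.37 and Lgals3, galectin 3, at −1.98 ± 0.24. Cav1 and Cavin2, parts of caveolae, fell by 1.71 ± 0.19 and 1.95 ± 0.18.

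In control cells 826 genes were higher and 408 lower with TGFβ1 at adjusted p below 0.05 (edgeR quasi-likelihood, n = 3 per group), 342 and 124 of them by 2-fold or more, and 3438 genes had an unadjusted p below 0.05. Without both TGFβ1 replicate 3 libraries 1988 were higher and 1426 lower, and leaving out control TGFβ1 replicates 1, 2 and 3 in turn gave 330, 262 and 1496 higher and 208, 146 and 904 lower. Leaving out untreated control replicates 1, 2 and 3 in turn gave 443, 291 and 309 higher and 262, 196 and 208 lower. Of 89 genes named by the rule and called in this comparison, 46 kept the call in each of the 6 such fits, among them Fn1, Tnc, Mmp9, Cdh1 and Il1a. With no filter on low counts 1404 genes were higher and 711 lower.

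TGFβ1 raised SMAD target genes in PBRM1 KO cells as well. Ccn2 rose by log2 2.64 ± 0.27 (adjusted p = 9.91e-05), Pmepa1, an inhibitor of SMAD signalling, by 1.37 ± 0.24 and Smad7 by 0.90 ± 0.22. Of 18 TGFβ-SMAD targets 14 rose and 0 fell, or 15 and 0 adjusted over the list alone (camera adjusted p = 5.66e-13, adjusted p = 0.194 with an estimated correlation). The estimated correlation gave adjusted p = 0.00823 without both TGFβ1 replicate 3 libraries. Of 6 BMP-SMAD and Id genes Id1 fell by 1.11 ± 0.16 and Id2 by 1.44 ± 0.19, and adjusted over the list alone 4 fell and 1 rose (camera adjusted p = 0.00433, adjusted p = 0.209 with an estimated correlation). That list did not pass without both replicate 3 libraries (adjusted p = 0.102). Of 20 YAP-TEAD targets 5 rose, with Amotl2 at 0.94 ± 0.17 and Dock5 at 0.41 ± 0.10, and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0032, adjusted p = 0.177 with an estimated correlation). With the replicate block 9 rose and 1 fell.

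Among mesenchymal genes 9 of 22 rose and 2 fell in PBRM1 KO cells, or 10 and 3 adjusted over the list alone and 9 and 4 with the replicate block (camera adjusted p = 0.00397, adjusted p = 0.201 with an estimated correlation). Fn1 rose by log2 1.70 ± 0.13, Itgb3 by 4.44 ± 0.63, Snai1 by 1.12 ± 0.24 and Zeb2 by 0.46 ± 0.09, and S100a4 fell by 2.16 ± 0.15 and the receptor kinase gene Axl by 0.60 ± 0.17. Vim was at −0.19 ± 0.14 (adjusted p = 0.393, and 0.00742 without both TGFβ1 replicate 3 libraries), Zeb1 at 0.90 ± 0.41 (adjusted p = 0.175), Snai2 at −0.45 ± 0.98 (adjusted p = 0.817) and Epcam at 0.30 ± 0.15 (adjusted p = 0.216, and 0.00155 without them). Of 36 epithelial genes 10 fell and 4 rose, or 10 and 5 adjusted over the list alone. Cdh1 fell by 0.59 ± 0.12, Krt19 by 0.80 ± 0.15 and Perp by 1.10 ± 0.09, while Cldn4, a tight junction protein, rose by 1.12 ± 0.20 and Jup, plakoglobin, went from 182 to 426 CPM (adjusted p = 0.0481). The epithelial list did not pass (camera adjusted p = 0.136), with a median of 0.05, a mean of −0.01 and direction down; the interaction of Cldn4 was 0.92 ± 0.27 (adjusted p = 1.00).

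Of 37 collagen and matrix assembly genes 15 rose and 1 fell in PBRM1 KO cells, or 18 and 2 adjusted over the list alone (camera adjusted p = 4.82e-07, adjusted p = 0.392 with an estimated correlation). Tnc rose by log2 4.38 ± 0.50 and Sparc by 1.37 ± 0.20, and Lama5 fell by 0.50 ± 0.10. Of 25 matrix proteases and inhibitors 9 rose and 2 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.00021, adjusted p = 0.115 with an estimated correlation). Mmp9 rose by 5.22 ± 0.55, Mmp13 by 3.91 ± 0.37, Mmp10 by 3.25 ± 0.33 and Adamts4 by 4.16 ± 0.69, and Adam8 and Adamts1 fell by 1.49 ± 0.19 and 1.28 ± 0.25. Of 22 actin and contractility genes 7 rose and 0 fell, with Pdlim7 at 0.62 ± 0.11 and Actn1 at 0.46 ± 0.10, and 10 rose adjusted over the list alone (camera adjusted p = 0.00136, adjusted p = 0.542 with an estimated correlation). With the replicate block 11 actin genes rose, and 19 matrix assembly genes rose and 2 fell.

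Of 30 mitosis genes 9 fell and 0 rose in PBRM1 KO cells, among them Anln by log2 −0.62 ± 0.13 and Ccna2, cyclin A2, by −0.50 ± 0.12, and 21 fell adjusted over the list alone (camera adjusted p = 1.49e-09, adjusted p = 0.194 with an estimated correlation). In S phase 3 of 32 genes fell, also 3 adjusted over the list alone, with Lig1 at −0.41 ± 0.12 (camera adjusted p = 7.76e-07, adjusted p = 0.501 with an estimated correlation). The S phase median was −0.02 in PBRM1 KO TGFβ1 replicate 3 and −0.34 and −0.35 in replicates 1 and 2, measured from untreated control cells. Of 32 hypoxia and glycolysis genes 8 fell and 1 rose, or 13 and 3 adjusted over the list alone, with Car9 at −0.77 ± 0.17, Pgam1 at −0.35 ± 0.09 and Vegfa at 2.73 ± 0.47 (camera adjusted p = 0.0032, adjusted p = 0.392 with an estimated correlation). Without both replicate 3 libraries the hypoxia list did not pass (adjusted p = 0.0987). Of 34 oxidative phosphorylation genes 1 rose and 0 fell, the same adjusted over the list alone, while the list was lower (camera adjusted p = 0.0175, adjusted p = 0.635 with an estimated correlation). Cholesterol synthesis had 1 rise and 1 fall among 24 genes, Sc5d at 0.38 ± 0.10 and Idi1 at −0.63 ± 0.18, also 1 and 1 adjusted over the list alone (adjusted p = 0.123). The replicate block gave more falls: 17 mitosis, 13 S phase, 14 hypoxia (with 4 rises), 3 oxidative phosphorylation and 6 cholesterol genes (with 2 rises).

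Of 25 chemokine, cytokine and NF-κB genes 9 rose and 0 fell in PBRM1 KO cells, or 9 and 1 adjusted over the list alone (camera adjusted p = 1.72e-05, adjusted p = 0.115 with an estimated correlation). Il1a went from 6.80 to 90.5 CPM (log2 3.72 ± 0.28), and Ccl20, a chemokine for dendritic cells and lymphocytes, rose by 2.08 ± 0.33 and Csf3 by 0.95 ± 0.21. Of 21 MHC class I presentation genes 5 rose, among them Psmb10, an immunoproteasome subunit, at 0.82 ± 0.19 and Erap1 at 0.75 ± 0.16, and 8 rose adjusted over the list alone (camera adjusted p = 0.000447, adjusted p = 0.516 with an estimated correlation). Of 34 interferon-stimulated genes 2 rose and 1 fell (Dtx3l 0.94 ± 0.28, Parp12 0.57 ± 0.17, Ifit2 −0.82 ± 0.18), or 9 and 1 adjusted over the list alone (camera adjusted p = 0.00148, adjusted p = 0.635 with an estimated correlation). With the replicate block 16 interferon genes rose and 1 fell, 9 MHC class I genes rose, and 10 NF-κB genes rose and 1 fell. Measured from untreated control cells, the interferon median was −0.29, −0.29 and −0.68 in untreated PBRM1 KO replicates 1, 2 and 3 and 0.24, 0.64 and −0.42 with TGFβ1. Without both TGFβ1 replicate 3 libraries 23 of these genes rose.

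The remaining lists did not pass in PBRM1 KO cells. Unfolded protein response and ATF4 targets had 6 rises and 1 fall among 26 (Xbp1 0.84 ± 0.15, Phgdh −0.50 ± 0.13; adjusted p = 0.123), NRF2 targets 4 and 4 among 22 (Ftl1 0.58 ± 0.10, Fth1 −0.66 ± 0.19; adjusted p = 0.239). Tumour-initiating and stem markers had 4 rises and 2 falls among 14 (Jag1 2.65 ± 0.37, Itga6 −1.35 ± 0.19; adjusted p = 0.71), and cell cycle inhibitors and p53 targets 1 and 2 among 17 (Cdkn1a 11.2 to 26.5 CPM, Cdkn2c −0.56 ± 0.13; adjusted p = 0.825). SWI/SNF subunits had 2 rises and 1 fall among 27 (Bcl7a 0.43 ± 0.12, Dpf1 −1.02 ± 0.30; adjusted p = 0.242), fibroblast markers 2 rises among 9 (C3 1.41 ± 0.34; adjusted p = 0.28) and mitochondrially encoded transcripts 0 of 15, or 2 falls with the replicate block (adjusted p = 0.153 without it). Adjusted over the list alone, rises and falls were 7 and 2 for the unfolded protein response, 4 and 5 for NRF2 targets, 4 and 2 for stem markers and for p53 targets, 2 and 1 for SWI/SNF subunits, 3 and 1 for fibroblast markers and 0 and 0 for mitochondrial transcripts. The replicate block gave 4 rises and 2 falls for p53 targets, 4 and 7 for NRF2 targets and 4 and 1 for SWI/SNF subunits. Outside the lists Mab21l4 rose by 5.04 ± 0.99, Hsd11b2 by 4.95 ± 0.60, Smoc1 by 4.63 ± 0.72, Col27a1 by 3.95 ± 0.74 and Clu, clusterin, by 3.58 ± 0.44. Dlk2 fell by 3.48 ± 0.47, Padi1 by 2.35 ± 0.36, Ptpn22 by 2.27 ± 0.66, Myh14 by 1.99 ± 0.35 and Lgals3 by 1.97 ± 0.24.

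In PBRM1 KO cells 1072 genes were higher and 521 lower with TGFβ1 (edgeR quasi-likelihood, n = 3 per group), 444 and 139 of them by 2-fold or more, and 3811 genes had an unadjusted p below 0.05. With the replicate number as a block 1682 genes were higher and 1098 lower. Without both TGFβ1 replicate 3 libraries 2277 were higher and 1707 lower, and leaving out PBRM1 KO TGFβ1 replicates 1, 2 and 3 in turn gave 450, 438 and 1726 higher and 181, 175 and 1333 lower. Leaving out untreated PBRM1 KO replicates 1, 2 and 3 in turn gave 489, 551 and 575 higher and 245, 261 and 302 lower. Of 107 genes named by the rule and called in this comparison, 56 kept the call in each of the 6 such fits, among them Fn1, Mmp9, Il1a and Cldn4. With no filter on low counts 1500 genes were higher and 913 lower.

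The plot of both TGFβ1 responses set the genotypes side by side. Of the called genes 638 were higher in both genotypes (63.2 expected by chance) and 262 lower in both (15.2 expected), and 0 were called in opposite directions (30.7 and 31.2 expected). The fold changes correlated with Pearson 0.855 (jackknife SE 0.0441) and Spearman 0.734 across 14012 genes, which are not independent of each other. Tnc, Mmp9, Fn1, Hsd11b2 and Itgb3 were among the shared rises and S100a4, Lgals3, Cav1 and Cdh1 among the shared falls.

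**Figure D2:**
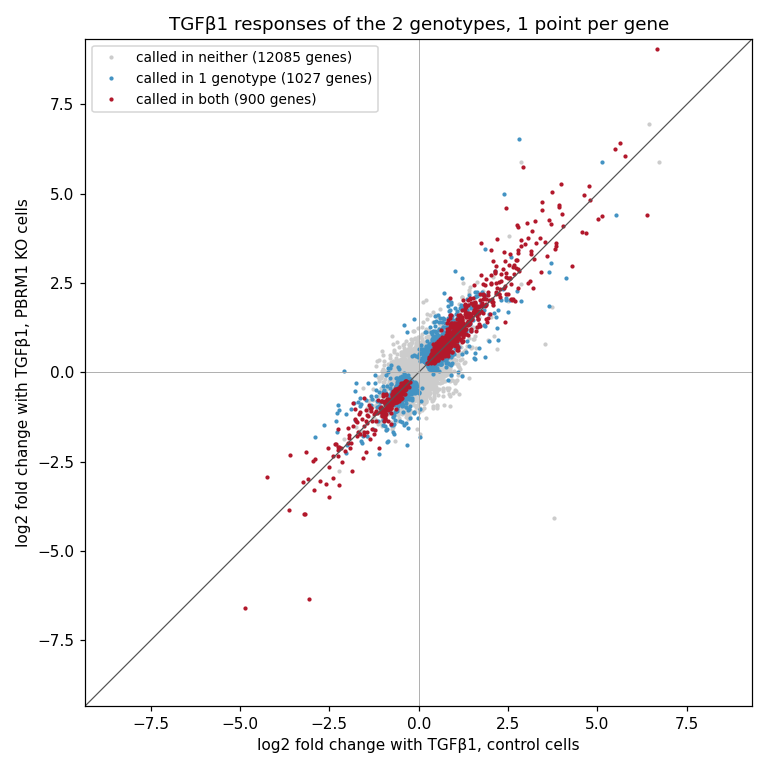
Log2 fold change with TGFβ1 in PBRM1 KO cells (vertical) against control cells (horizontal), 1 point per tested gene. Colours mark the 900 genes called in both genotypes and those called in 1 genotype only, with the rest in grey.

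Of the genes called without TGFβ1 with at least 10 CPM, Lcn2 and Il1a had the largest falls in PBRM1 KO cells. Lcn2, an iron-siderophore-binding acute phase protein, went from 31.9 ± 6.72 CPM in control to 1.06 ± 0.339 CPM in PBRM1 KO cells (log2 −4.90 ± 0.40, adjusted p = 6.08e-05, n = 3). Il1a went from 107 to 6.80 CPM (log2 −3.98 ± 0.28, adjusted p = 3.16e-05). Ccl20 fell by 2.78 ± 0.32, Cxcl1, a neutrophil chemokine, by 2.32 ± 0.41 and Csf3, the granulocyte colony-stimulating factor, went from 51.5 to 18.2 CPM (adjusted p = 0.00746). Of 25 chemokine, cytokine and NF-κB genes 6 fell and 0 rose, and 12 fell adjusted over the list alone. The list was lower with camera adjusted p = 2.58e-38 and adjusted p = 0.000294 with an estimated correlation. Its lowest control library lay 0.292 log2 above its highest PBRM1 KO library in the list median.

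Other genes lower in untreated PBRM1 KO cells were Slpi, a secreted protease inhibitor, at log2 −2.47 ± 0.46, Neurl3 at −2.40 ± 0.19, Slc4a4 at −1.72 ± 0.20, Ly6e at −1.32 ± 0.19 and Nfkbiz, a nuclear IκB protein, at −1.02 ± 0.16. Of 36 epithelial genes 2 fell: Elf3, an epithelial ETS factor, by 0.80 ± 0.13, and Ehf, with 3 counts against 72, 25.3-fold lower (95% interval 8.33 to 126). Adjusted over the list alone 9 fell (camera adjusted p = 2.08e-12, adjusted p = 0.105 with an estimated correlation, fry adjusted p = 0.0459). Of 34 interferon-stimulated genes Oasl1, Cxcl10 and Rsad2 fell by 1.48 ± 0.26, 1.32 ± 0.22 and 2.23 ± 0.36, and 6 fell adjusted over the list alone (camera adjusted p = 2.01e-11, adjusted p = 0.349 with an estimated correlation). Of 21 MHC class I presentation genes 2 fell, Nlrc5, the transactivator of these genes, by 1.69 ± 0.21 and H2-D1 by 0.75 ± 0.13, and 3 fell adjusted over the list alone (camera adjusted p = 7.79e-07, adjusted p = 0.349 with an estimated correlation). H2-D1 had fractional counts in 11 of 12 libraries, so reads shared with other class I genes entered its value. Espn, an actin bundler, was the only rise under the naming rule, by 1.31 ± 0.24 (adjusted p = 0.0346).

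**Figure D3:**
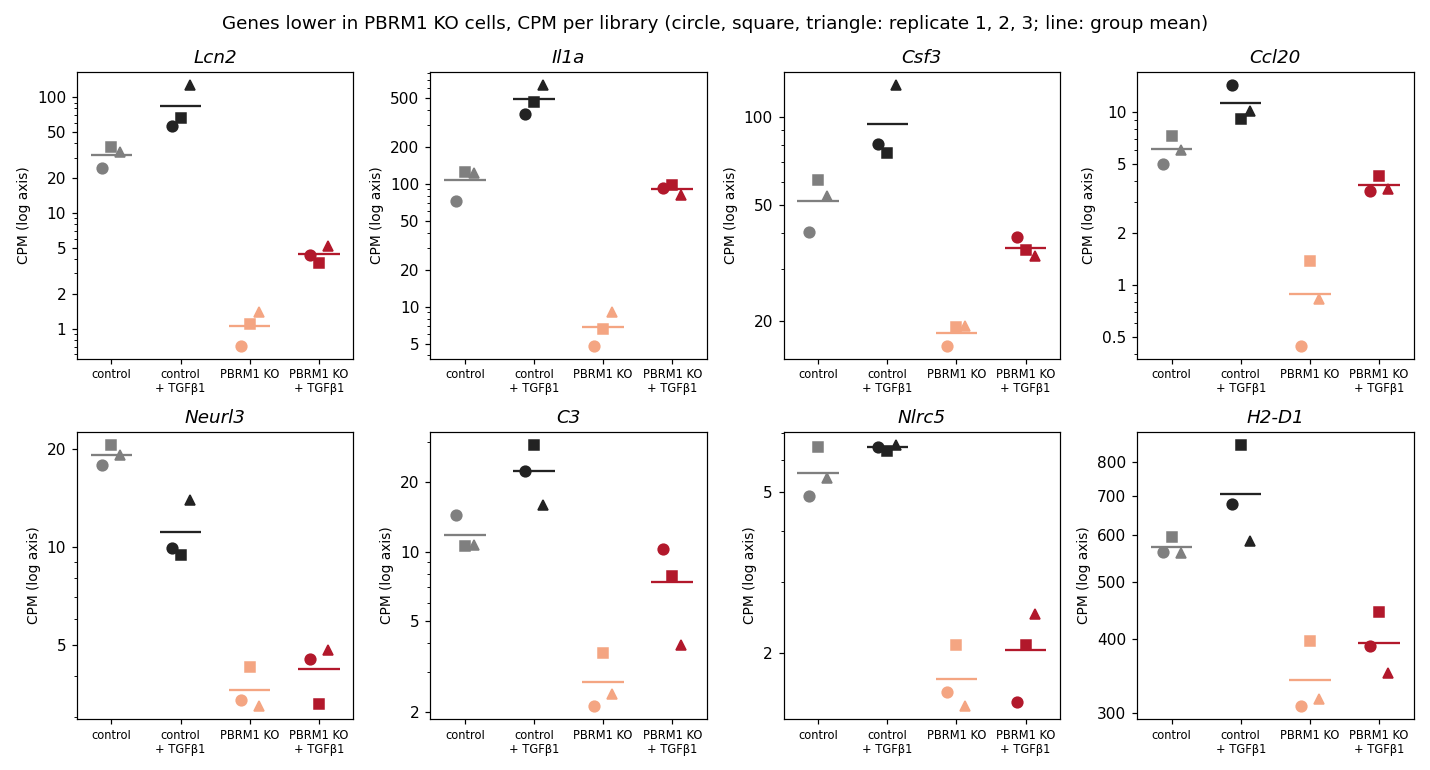
CPM of 8 genes in the 4 groups on log axes, 1 point per library and n = 3 per group. The group means of Lcn2 were 31.9 and 83.6 CPM in control cells and 1.06 and 4.40 CPM in PBRM1 KO cells, untreated and with TGFβ1.

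Several lists moved in untreated PBRM1 KO cells with few or 0 passing genes. The proteases had 0 of 25 passing and 2 falls adjusted over the list alone (camera adjusted p = 0.00107, adjusted p = 0.109 with an estimated correlation, fry adjusted p = 0.0459). Fibroblast markers had 1 fall of 9, C3, complement component 3, by log2 −2.12 ± 0.33, also 1 adjusted over the list alone (camera adjusted p = 0.00145, adjusted p = 0.349 with an estimated correlation). Cholesterol synthesis, 0 of 24 and 0 adjusted over the list alone, was lower with camera adjusted p = 7.72e-06 and adjusted p = 0.349 with an estimated correlation. Hypoxia and glycolysis, 0 of 32 and 2 falls adjusted over the list alone, was lower with adjusted p = 0.00418 and adjusted p = 0.349 with an estimated correlation. The BMP-SMAD and Id list was higher, 0 of 6 and 1 rise adjusted over the list alone (adjusted p = 0.00517, adjusted p = 0.334 with an estimated correlation), with Id2 at 0.59 ± 0.18 (adjusted p = 0.352).

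No other list passed in untreated PBRM1 KO cells. Camera gave adjusted p = 0.416 for the 18 TGFβ-SMAD targets (Smad7 log2 0.01 ± 0.23), which gave 0.0108 downwards without both TGFβ1 replicate 3 libraries, 0.92 for 22 mesenchymal genes, 0.928 each for 37 matrix, 22 actin, 20 YAP-TEAD and 30 mitosis genes, and 0.485 for 27 SWI/SNF subunits. The mesenchymal test pointed up with a median of −0.06 and a mean of −0.16. Vim was at 0.61 ± 0.14 (edgeR adjusted p = 0.109, 0.00109 without both TGFβ1 replicate 3 libraries and 0.00559 with the replicate block). Cdh1 was at 0.02 ± 0.12, Fn1 at −0.01 ± 0.13, Snai1 at −0.34 ± 0.24 and Zeb2 at 0.26 ± 0.10. For 32 S phase genes and 14 stem markers the value was 0.116 each (0.0344 for stem markers without both replicate 3 libraries), for 34 oxidative phosphorylation genes 0.305, for 17 p53 targets 0.205, for 26 unfolded protein response genes 0.0654, for 22 NRF2 targets 0.103 and for 15 mitochondrial transcripts 0.536.

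Without TGFβ1 6 genes were higher and 33 lower in PBRM1 KO cells (edgeR quasi-likelihood, n = 3 per group), 5 and 25 of them by 2-fold or more, and 1065 genes had an unadjusted p below 0.05. DESeq2 called 25 and 78, an edgeR fit on only the 6 libraries 34 and 101, no filter on low counts 87 and 191, and genes of at least 10 CPM alone gave 1 and 16. Without both TGFβ1 replicate 3 libraries in the shared fit 56 were higher and 145 lower. Neither library belongs to this contrast, so they acted only through the filter, scaling and error estimate of the shared fit. The 6 and 33 calls of the main fit thus depended on libraries of other groups. With the replicate number as a block 39 were higher and 105 lower. This contrast was not taken as paired, a verdict that depended on which genes were used. Leaving out untreated control replicates 1, 2 and 3 in turn gave 3, 0 and 0 higher and 14, 13 and 24 lower. Leaving out untreated PBRM1 KO replicates 1, 2 and 3 gave 0, 0 and 0 higher and 9, 23 and 8 lower. Lcn2, Il1a, Ccl20, Neurl3, Nlrc5 and Slc4a4, 6 of the 19 genes named by the rule and called, kept the call in each of these fits.

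With TGFβ1 Lcn2, Slpi and Il1a had the largest falls in PBRM1 KO cells among called genes with at least 10 CPM. Lcn2 went from 83.6 to 4.40 CPM (log2 −4.25 ± 0.32, adjusted p = 7.00e-05, n = 3) and Il1a from 493 to 90.5 CPM (−2.46 ± 0.24, adjusted p = 0.000753). Slpi fell by 2.98 ± 0.45, C3 by 1.62 ± 0.29, Ccl20 by 1.57 ± 0.24, Csf3 by 1.43 ± 0.20 and Slc4a4 by 1.13 ± 0.18. Of 25 chemokine, cytokine and NF-κB genes 6 fell and 0 rose, and 13 fell adjusted over the list alone. The list was lower with camera adjusted p = 7.79e-27 and adjusted p = 0.000892 with an estimated correlation, and with the replicate block the estimated correlation gave adjusted p = 0.011. The gap between its lowest control and highest PBRM1 KO library was 0.415 log2 in the list median.

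Of 21 MHC class I presentation genes 2 fell in PBRM1 KO cells with TGFβ1, Nlrc5 by log2 −1.66 ± 0.20 and H2-D1 by −0.85 ± 0.13, and 4 fell adjusted over the list alone (camera adjusted p = 0.00111, adjusted p = 0.983 with an estimated correlation). Of 34 interferon-stimulated genes 0 passed, 5 fell with the replicate block, Cxcl10 (adjusted p = 0.0436) and Rsad2 (adjusted p = 0.0432) among them, and 3 fell adjusted over the list alone (camera adjusted p = 0.00127, adjusted p = 0.983 with an estimated correlation). Of 25 proteases 1 fell, Mmp13, a collagenase, by 1.58 ± 0.24, also 1 adjusted over the list alone (camera adjusted p = 0.00173, adjusted p = 0.172 with an estimated correlation). Fibroblast markers had 1 fall of 9, C3, and 2 adjusted over the list alone (camera adjusted p = 0.0249, adjusted p = 0.983 with an estimated correlation), and did not pass with the replicate block (adjusted p = 0.0619). The block gave 4 falls each for MHC class I presentation and proteases. Outside the lists Plac9 fell by 1.28 ± 0.20, Glrx, glutaredoxin, by 1.14 ± 0.15 and Ly6e by 1.04 ± 0.20. Rcor2 rose by 0.80 ± 0.14, Nfe2l3 by 0.76 ± 0.12, Cuedc1 by 0.65 ± 0.11 and Ankrd13b by 0.46 ± 0.08, and Tubb2b, whose counts were fractional in all 12 libraries, by 0.85 ± 0.14.

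**Figure D4:**
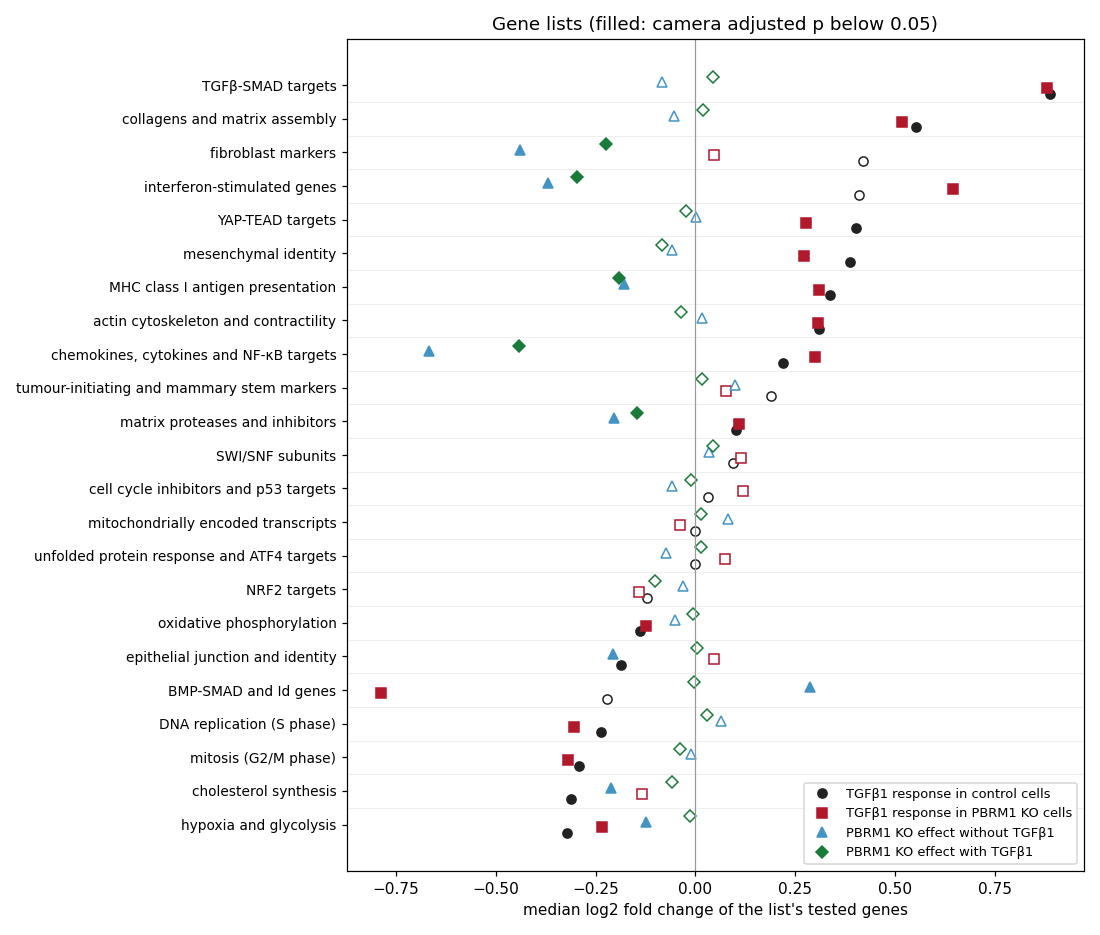
Median log2 fold change of the tested genes of each list (horizontal) in the 4 pairwise comparisons, 1 point per list and comparison. Filled points passed camera at the preset correlation; the NF-κB list lay at −0.67 for PBRM1 KO without TGFβ1 and −0.44 with it.

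The SMAD target, mesenchymal, matrix assembly and epithelial lists did not pass between genotypes with TGFβ1. Camera gave adjusted p = 0.847 for the 18 TGFβ-SMAD targets, with Smad7 at log2 −0.11 ± 0.22, 0.652 for 22 mesenchymal genes with Fn1 at 0.04 ± 0.12, and 0.847 for 37 matrix genes with Sparc at 0.48 ± 0.19. The 36 epithelial genes gave 0.652 with Cdh1 at 0.18 ± 0.12; Elf3 was at −0.60 ± 0.13 (adjusted p = 0.0923, and 0.0296 with the replicate block) and Ehf at −2.68 ± 0.55 (adjusted p = 0.0732, and 0.00323 with the block). For 6 BMP-SMAD and Id genes the value was 0.809, with Id1 at −0.75 ± 0.16 (adjusted p = 0.092, and 0.0338 with the block), for 22 actin genes 0.935 and for 34 oxidative phosphorylation genes 0.943. YAP-TEAD, hypoxia, mitosis, p53, cholesterol and SWI/SNF lists each gave 0.644, S phase 0.732, unfolded protein response and mitochondrial transcripts 0.847, NRF2 targets 0.196 and stem markers 0.652. With the replicate block 1 SMAD target and 1 mitochondrial transcript fell, 1 hypoxia gene rose, and 1 NRF2 target rose and 1 fell.

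With TGFβ1 10 genes were higher and 28 lower in PBRM1 KO cells (edgeR quasi-likelihood, n = 3 per group), 4 and 20 of them by 2-fold or more, and 1194 genes had an unadjusted p below 0.05. With the replicate number as a block 49 were higher and 109 lower. DESeq2 called 21 and 58, no filter on low counts gave 78 and 181, genes of at least 10 CPM alone 5 and 16, and a fit on only the 6 libraries 0 and 4. Leaving out control TGFβ1 replicates 1, 2 and 3 in turn gave 0, 0 and 13 higher and 10, 11 and 48 lower, and PBRM1 KO TGFβ1 replicates 1, 2 and 3 gave 1, 0 and 10 higher and 17, 3 and 23 lower. Without both replicate 3 libraries 21 were higher and 55 lower. Lcn2 and Il1a, 2 of the 18 genes named by the rule and called, kept the call in each leave-one-out fit.

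Across both states 17 genes were lower in PBRM1 KO cells with and without TGFβ1 (0.0659 expected by chance) and 2 were higher (0.00428 expected). The shared falls included Lcn2, Il1a, Ccl20, Csf3, Slpi, C3, Slc4a4, Ly6e, Nlrc5 and H2-D1, and Espn was a shared rise. Acod1, which encodes the itaconate-producing enzyme of activated macrophages, had 0 counts in untreated PBRM1 KO cells against 24, at least 8.45-fold lower, and 1 count against 72 with TGFβ1. Nos2 had 2 counts against 50 without TGFβ1, 26.4-fold lower (95% interval 6.93 to 224). The 2 genotype effects correlated with Pearson 0.513 (jackknife SE 0.103) and Spearman 0.409 across 14012 genes.

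The interaction of genotype and TGFβ1 called 0 genes higher and 0 lower in edgeR (n = 3 per group), with 247 genes at an unadjusted p below 0.05 and a smallest adjusted p = 1.00. DESeq2 called 0 with 164 such genes, and limma-voom 0 with 255. The 247 genes were 1.76% of those tested, under the share of 0.05 that follows where nothing differs. The edgeR test was therefore strict here and could miss real differences. Without both TGFβ1 replicate 3 libraries 487 of 14260 genes had such a p, with 0 called. With no filter on low counts edgeR called 8 higher and 10 lower, with Il1a, Cldn4 and Id1 among them; that setting was not tested on simulated data. Il1a had an interaction of log2 1.52 ± 0.36, since TGFβ1 raised it by 2.20 in control and 3.72 in PBRM1 KO cells, and Ccl20 had 1.21 ± 0.41 and Id1 −0.97 ± 0.22. An unadjusted interaction p below 0.05 was found for 113 of 1927 genes called in either genotype and for 20 of 900 called in both. Adjusted over the list alone 1 of 25 NF-κB genes passed upwards, and 1 of 6 BMP-SMAD and Id genes downwards.

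For the interaction 5 lists passed camera at the preset correlation and 0 with an estimated correlation. All 5 had also passed for genotype without TGFβ1 in the opposite direction, an effect that the interaction subtracts on the same untreated libraries. The 36 epithelial genes were higher, 33 with a positive value, among them Cldn4 at log2 0.92 ± 0.27 and Rab25 at 0.80 ± 0.26 (adjusted p = 1.29e-09, adjusted p = 0.342 with an estimated correlation). Cholesterol synthesis was higher (Fdps 0.44 ± 0.23, adjusted p = 0.00196, adjusted p = 0.982 with an estimated correlation), and did not pass without both TGFβ1 replicate 3 libraries (adjusted p = 0.0556). The interferon list (Oasl1 0.98 ± 0.36, adjusted p = 0.0065, adjusted p = 0.982 with an estimated correlation) and the NF-κB list (adjusted p = 0.00812, adjusted p = 0.406 with an estimated correlation) were also higher. BMP-SMAD and Id genes were lower (Id1, and Id2 at −0.67 ± 0.27; adjusted p = 0.00196, adjusted p = 0.342 with an estimated correlation). The other lists gave adjusted p of 0.144 or more, among them 0.384 for TGFβ-SMAD targets, which gave 0.00472 without both replicate 3 libraries, 0.407 for mesenchymal and 0.895 for matrix genes.

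The genotype effect without TGFβ1 and the TGFβ1 response of control cells share the 3 untreated control libraries. Their fold changes correlated at Pearson −0.06 (jackknife SE 0.166) across 14012 genes. In 20 simulations of unchanged groups that share those libraries the correlation was 0.499. The simulations held no TGFβ1 response, whose added spread shrinks a correlation, so these 2 values are not comparable. The covariance was −0.0102 (jackknife SE 0.0353) against 0.0272 in the simulations. Of 33 genes lower in PBRM1 KO cells 9 were higher with TGFβ1 in control cells (1.95 expected for independent lists) and 6 were lower (0.961 expected). Shared libraries alone make the first kind rarer and the second more common. Lcn2, Il1a, Ccl20 and Csf3 were among the 9.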

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

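All tests of explanations below were chosen after the results were seen; only the regroupings of libraries were planned before. Because groups held 3 libraries, no single library was tested as apart from its group.

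In the interaction of genotype and TGFβ1, 5 lists passed camera at the preset correlation: BMP-SMAD and Id genes (adjusted p = 0.00196), epithelial genes (adjusted p = 1.29e-09), interferon-stimulated genes (adjusted p = 0.0065), chemokine, cytokine and NF-κB genes (adjusted p = 0.00812) and cholesterol synthesis (adjusted p = 0.00196). Each was singled out because it differed between the genotypes in its response, and with an estimated correlation the values were 0.342, 0.342, 0.982, 0.406 and 0.982.

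The epithelial list is the largest of these, with 33 of 36 genes on the same side and 0 passing alone. Members that vary together between replicates might account for it: camera with a correlation estimated from the residuals gave adjusted p = 0.342, so that explanation stays possible. Those residuals also hold the smaller response of TGFβ1 replicate 3. The same setting lost 45 of 47 list calls over all contrasts, so a value that does not pass adds no weight to the explanation. A real difference in epithelial genes was not excluded either, and no error was estimated for that correlation.

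TGFβ1 replicate 3 of both genotypes showed a smaller response, at 0.328 and 0.463 of the axis. Lower depth is not the cause, since its total was 1.06 times that of the other TGFβ1 libraries, and neither is a swap, since no untreated library lay above 0.125. Mixing with untreated cells or RNA was tested in 3 ways. Genes picked in 1 genotype and read in the other lay below every untreated library in replicate 3 in 37.5 ± 4.96% (control) and 24.8 ± 4.27% (PBRM1 KO) of cases, where 25% follows from no change, which did not decide. Genes that fell kept 16.1 ± 6.31 points more of the response than genes that rose in control and 30.6 ± 3.87 in PBRM1 KO cells, while replicate 1 against 2 gave 5.29 and −14.9 points, so that test, whose bound was tightened once the values were known, did not decide either. The third test, chosen after these, used 235 rises and 57 falls picked without replicate 3. It asked whether each gene kept the same share, as mixing with material like the untreated libraries requires. The share kept ran from 2.17 to 60.2% for rises in control and from 9.02 to 58.0% in PBRM1 KO cells (10th to 90th percentile). It correlated between the genotypes at Spearman 0.839 ± 0.0223 for rises and 0.816 ± 0.0571 for falls, against 0.257 and 0.161 for replicate 1 against 2. The values speak against mixing with material like the untreated libraries as the whole cause, although the bootstrap treats genes as independent. Untreated material that differed from these libraries was not excluded, nor was mixing beside a deviation shared by replicate number. Both could give kept shares that correlate between the genotypes. Whether a weaker or shorter exposure or another day lies behind the smaller response was not tested. No biological explanation was tested either, since the design names no group for it.

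The lower NF-κB and cytokine genes of PBRM1 KO cells might come from leukocyte RNA in the control cultures. The 24 leukocyte markers summed to 0.816 times as much in control as in PBRM1 KO libraries, with Ptprc at most 0.181 CPM, which speaks against it; Cd68 made up 44.0 to 79.3% of that sum, and without it the ratio was 0.954. The values also speak against fibroblast RNA as the whole cause. The 16 fibroblast markers were lower in PBRM1 KO cells by 55.1 ± 16.3 CPM in sum without and 21.3 ± 45.3 with TGFβ1 (± SE, n = 3). The 25 NF-κB and cytokine genes were lower by 465 ± 82.1 and 796 ± 121, so the markers' share was 0.118 at most, while fibroblasts carry abundant collagen transcripts. Gsn dominated the marker sum, at 355, 292 and 318 CPM in untreated control replicates 1, 2 and 3, where the sum averaged 379. C3, also among the markers, was itself called lower in PBRM1 KO cells. A single library as the cause is also not supported: the list median of the lowest control library lay 0.292 above the highest PBRM1 KO library without TGFβ1 and 0.415 with it. Whether the 2 lines differed for reasons other than PBRM1, such as clonal origin, was not tested, because no label names independently derived lines.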

How the results depend on the processing

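The values below come from edgeR unless another tool is named, as genes higher and lower. No count changed direction, and the cause of lost or gained calls was not tested. The TGFβ1 replicate 3 libraries could act on genotype without TGFβ1 only through the shared fit, since neither belongs to that contrast. RLE and library-size scaling and unrounded counts moved no count by over 1.5 times. Of 233 calls of named genes, RLE lost 1, library size 9, DESeq2 6, no filter 9, limma-voom 27, the 6-library fits 38, unrounded counts 0, and at least 10 CPM 6 of 210. Single left-out libraries lost 482 of 1398 such calls. Of 47 list calls 45 were lost with an estimated correlation; only the NF-κB list in both genotype contrasts kept its call. Of the 47, fry passed 22: 9 of 14 for TGFβ1 in control cells, 9 of 14 in PBRM1 KO cells, 3 of 9 and 1 of 5 for genotype without and with TGFβ1 and 0 of 5 for the interaction. Without both TGFβ1 replicate 3 libraries, an alternative added after the data were seen like the unrounded counts, 4 list calls were lost and 4 gained.

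No filter on low counts gave 1404 and 711 for TGFβ1 in control cells, 913 lower for TGFβ1 in PBRM1 KO cells, 87 and 191 for genotype without TGFβ1, 78 and 181 with it, and 8 and 10 for the interaction. At least 10 CPM gave 1 and 16 for genotype without TGFβ1 and 5 and 16 with it, 0 higher and 7 lower in both states, and Pearson 0.904 between the TGFβ1 responses. DESeq2 gave 25 and 78 for genotype without TGFβ1, 21 and 58 with it, 8 higher and 34 lower in both, and 22 lower with KO and higher with TGFβ1. The 6 libraries of a contrast alone gave 34 and 101 without and 0 and 4 with TGFβ1. Adjusted p below 0.01 gave 201 and 80 shared between the TGFβ1 responses, 0 and 3 in both genotype contrasts, and 2 lower with KO and higher with TGFβ1.

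Without both TGFβ1 replicate 3 libraries counts were 1988 and 1426 (TGFβ1, control), 2277 and 1707 (TGFβ1, PBRM1 KO), 56 and 145 (genotype without TGFβ1) and 21 and 55 (with it), with 1661 and 1090 shared TGFβ1 calls, 10 and 36 in both genotype contrasts, and 68 lower with KO and higher with TGFβ1. Leaving out each library in turn gave 262 to 1496 and 146 to 904 (TGFβ1, control), 438 to 1726 and 175 to 1333 (TGFβ1, PBRM1 KO), 0 to 3 and 8 to 24 (genotype without TGFβ1), 0 to 13 and 3 to 48 (with it), and 0 for the interaction.

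With the replicate number as a block counts were 1507 and 890 (TGFβ1, control), 1682 and 1098 (TGFβ1, PBRM1 KO), 39 and 105 (genotype without TGFβ1), 49 and 109 (with it) and 0 for the interaction; all calls of named genes were kept. For list tests the block lost 1 call (fibroblast markers, genotype with TGFβ1, adjusted p = 0.0619) and gained 2 (interferon, TGFβ1 in control, adjusted p = 0.0216; unfolded protein response, genotype without TGFβ1, adjusted p = 0.0465). It also gained calls of named genes in the paired contrasts: 9 for genotype with TGFβ1, among them Cxcl10 (adjusted p = 0.0436) and Rsad2 (adjusted p = 0.0432), and 1 mitochondrial transcript for TGFβ1 in PBRM1 KO cells (adjusted p = 0.0155). In the other pairwise contrasts it gained 8 for genotype without TGFβ1 and 2 for TGFβ1 in control cells. The 8 included Vim (adjusted p = 0.00559) and Serpinb5 (adjusted p = 0.00148). For the paired contrasts the counts of list members it moved stand in the report, and it changed no other list call. Same-numbered deviations correlated at 0.258, −0.0835 and 0.137 for TGFβ1 in control cells and 0.149, 0.069 and 0.125 for genotype without TGFβ1, so these were not taken as paired; 3 and 5 of 6 libraries lay closest to their own number. With genes above a mean log2 CPM of 3 the second set was 0.327, 0.116 and 0.273, so that verdict depends on the filter.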

Other observations

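Inside single lists members parted in direction. With TGFβ1 Manf (0.38 ± 0.07) and Pdia4 (0.42 ± 0.10) of the unfolded protein response list rose in control cells while Psat1 (−0.70 ± 0.19) fell; 9 of the 26 rose, 3 fell and no part of the list was tested on its own. In PBRM1 KO cells the ferritin genes parted, with the light chain Ftl1 at 0.58 ± 0.10 and the heavy chain Fth1 at −0.66 ± 0.19; both had fractional counts in 8 or more libraries. Among integrins Itgb1 rose by 0.35 ± 0.08 and Itgb3 by 4.02 ± 0.62 in control cells, and Itga6, a basal mammary marker, fell by 0.98 ± 0.19. Among mitosis genes 29 of 30 had a negative value in control cells and 30 of 30 in PBRM1 KO cells.

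A hypothesis is that PBRM1 holds up a basal NF-κB and interleukin 1 program in 4T1 cells. This program could still rise over 4 days with TGFβ1 when PBRM1 is absent. Il1a, Lcn2, Ccl20 and Csf3 were lower in PBRM1 KO cells in both states and rose with TGFβ1 in both genotypes, and the list passed with an estimated correlation without TGFβ1 (adjusted p = 0.000294) and with it (adjusted p = 0.000892). The untreated samples were 0 h, so a rise from TGFβ1 cannot be told from 1 over the 4 days. Il1a was at 374, 465 and 640 CPM in control TGFβ1 replicates 1, 2 and 3, and Lcn2 at 56.4, 66.4 and 128. Both were thus highest in replicate 3, whose TGFβ1 response was smaller. In PBRM1 KO cells with TGFβ1 Il1a was at 92.4, 97.4 and 81.8 CPM and Lcn2 at 4.34, 3.68 and 5.18. The leukocyte marker ratio of 0.816 speaks against leukocyte RNA. The fibroblast marker share of 0.118, from a sum dominated by Gsn, speaks against fibroblast RNA as the whole cause. Since Il1a itself activates NF-κB, loss of 1 cytokine in the line could carry the other genes; the data hold no test of order. A rescue with PBRM1 or added interleukin 1α, in independently derived lines, would separate these.

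That genes lower in PBRM1 KO cells tend to be genes that TGFβ1 raises stays open. The covariance of the 2 fold changes was −0.0374 relative to simulated groups that share the untreated control libraries, against a jackknife SE of 0.0353, so it was not shown across all genes. Among the 33 lower genes 9 were raised by TGFβ1 (1.95 expected for independent lists) and 6 were lowered (0.961 expected). Shared libraries make the first kind rarer and the second more common. The called genes thus exceeded the expected overlap in both directions. Whether rises outweighed falls among them was not tested.

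Regroupings of the libraries were planned to show how many calls chance alone gives. For the 4 pairwise contrasts only 10 splits exist, of which 1 was the real grouping, too few for a share under 0.05. The real counts were 1234, 1593, 39 and 38 and the highest other count was 0 each time. Every other split mixes both real groups on each side, so a real effect widens the spread within its groups. Those counts of 0 therefore say little about chance. For the interaction the real count was 0, which 100 of 100 splits reach by design, so they say nothing about chance; the highest other was 274, in the split that exchanges the genotype labels of all TGFβ1 libraries and so adds up the 2 genotype effects.

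A weaker TGFβ1 response without PBRM1 makes the difference between the responses, PBRM1 KO minus control in the direction of the response, negative. The median of this difference was log2 0.0888 for the 1927 genes called in either genotype and 0.0501 for the 900 called in both. No error was estimated for these medians and the genes were picked for their response. The first set leans to PBRM1 KO cells, with 1593 calls against 1234 in control cells. The smaller response of TGFβ1 replicate 3 enters both genotypes and need not be equal in them. A weakening was thus not seen but not excluded. The interaction test recovered 53.7% of 2-fold differences on simulated data, whose libraries were drawn independently. In the real data same-numbered TGFβ1 libraries of both genotypes deviated together (correlations 0.396, 0.416 and 0.726). The recovered share need not hold there, so 2-fold and smaller differences in single genes stay open.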
